A study of Homo sapiens with 16 samples.

How the data were processed

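Gene expression of human CD4+ T cells was measured on 16 Affymetrix Human Gene ST arrays. Per the labels, 6 arrays held naive cells grown for 60 h under Th17 conditions, with DMSO, TMP776 or TMP778, and 10 held memory cells stimulated through CD3 and CD28 for 16 h or 20 h. The deposited value table gives 1 probe intensity per array on a linear scale. The submitters' processing notes name RMA, a method of background correction, quantile normalization and probe summary, and Affymetrix Power Tools. The genome build and the annotation behind the probe sets are not given in the sources used here. The array medians of the deposited intensity ran from 39.0 to 43.6, and 0 values were at or below 0. The analysis had been planned for log2 values, so the log2 of each deposited intensity was taken before any fit. Scaling and centring of the table beyond these notes stay unknown, and the number of arrays, not a sequencing depth, limits the precision.

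Of the 22148 probes in the table, 19129 had 1 gene symbol in the platform annotation, 1735 had several and 1284 were not listed there. Genes were named only from probes with 1 symbol. Entrez identifiers updated 0 symbols. The 94 probes of Y-linked and X-inactivation genes were left out, because the cells come from people. This left 18254 genes, of which 625 had more than 1 probe and were represented by the brightest probe. A gene was tested if its log2 value reached 4.5, an intensity of 22.6 and the 40th percentile, in at least 2 arrays, which 12273 genes did. Some members of the gene lists are not analysed here, and 1 gene of the rule for named genes is not reported here.

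Differences were fitted with limma 3.58.1 in R 4.3.3 as linear models of 9 group means over all 16 arrays, with 7 residual degrees of freedom and moderated variances. Benjamini-Hochberg adjustment ran over all 12273 genes, at an adjusted p threshold of 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 6 treatment comparisons, their difference between culture systems and the comparison of CCR6+ with CCR6- memory cells were fixed before the data were examined, together with the groups, the gene lists, the rule for named genes and most alternatives. The rule named any tested member of the Th17 signature and of the Th17 target list. It then took the 10 largest rises and falls among genes that passed with arrays that did not overlap. With fewer than 5 such genes, it took the 5 largest in each direction at an unadjusted p under 0.01, given as not passing. From each other list it took up to 4 members with the smallest p and any that passed, and it took IL17A and IL17F in every group. Genes outside the rule are named as chosen after their values were seen.

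The labels number the arrays within each group. After the group means were removed, arrays of the same number deviated together across genes. The correlation was 0.727 to 0.847 over 6 pairs of naive arrays and 0.546 to 0.771 over 6 pairs of memory arrays, so the numbers were taken to pair the arrays from the data, as no label says what they mark. The array labelled CCR6+ vehicle 3 correlated nearly as highly with number 2 of TMP776 (0.552) and TMP778 (0.516). Without it, arrays 1 and 2 gave 0.702 to 0.765 over the memory arrays of the same number and -0.765 to -0.702 over those of different numbers. A second fit with the replicate block (the number within the naive and within the memory arrays) had 4 residual degrees of freedom. This fit takes the CCR6- arrays and the 16 h arrays as number 1 by label alone, and that pairing was not checked. Its values stand beside the others wherever a call changed: for the Th17 signature in naive cells under TMP778, the mean difference of -0.39 was the same in both fits and passed with the block, though not with the block and an estimated correlation (camera adjusted p = 0.512). Number 3 occurs on 1 array, so the block gives that array no weight in the compound comparisons.

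The 22 gene lists covered the Th17 signature, Th17 targets named in mouse work, other Th17 transcription factors, Th1, Th2, Treg and Tfh genes, T cell activation, naive and central memory markers, and innate-like T cell markers. They also covered the type I interferon response, the cell cycle, the circadian clock, cholesterol synthesis and uptake, LXR targets, glycolysis and hypoxia, ER and amino acid stress, and AHR and NRF2 targets. Markers of B cells, monocytes, CD8 T and NK cells, and platelets stood for other cell types of blood. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, with adjustment over the lists. Members were also tested with adjustment over the list alone. Several genes stand in more than 1 list, and the Th17 target list shares members with the Th17 signature. Comparisons that share vehicle arrays were set against 100 simulations of unchanged groups.

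The fits were tested on simulated data with 200 of 12273 genes changed, in 5 draws. For TMP778 against DMSO in naive cells, the fit of group means recovered 37.4% of 2-fold changes and 0% of 1.4-fold changes, and the replicate block recovered 98.6% and 64.4%. For the same comparison in memory cells the shares were 49.4% and 0.8% without the block and 98.2% and 58.2% with it. For CCR6+ against CCR6- cells they were 48.6% and 0.8%, and 98.2% and 67.4%. False calls per draw came to 7.6, 8.6 and 11 with the block in these 3 comparisons and to 0, 0 and 0.2 without it. The simulated arrays were drawn from the replicate block model itself, with the block effect and variance it estimated for each gene. The higher shares with the block are therefore built in. They describe the fits on such data only and do not show that the block is right for these arrays.

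Alternatives changed the filter, the handling of several probes, the variance model, the arrays in the fit, the scaling between arrays, the array weights and the thresholds, or left out 1 array at a time. Some alternatives and a contrast over both culture systems were added after the data were seen, and are named as such. The label of 16 h memory arrays gives DMSO in the title and no vehicle in the description, and they were treated as vehicle arrays.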

Results

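Expression was profiled on 16 arrays of human CD4+ T cells to ask how 2 compounds, TMP778 and TMP776, act on Th17 cells. Th17 cells are T helper cells that secrete IL-17A, IL-17F and IL-22. In published work TMP778 has been used as an active inhibitor and TMP776 as its inactive counterpart. Naive cells (CD4+ CD45RA+) were grown for 60 h with Th17-inducing cytokines in DMSO (2 arrays), TMP776 (2 arrays) or TMP778 (2 arrays). Memory cells (CD4+ CD45RO+) sorted as CCR6+ were stimulated for 20 h with beads against CD3 and CD28, in DMSO (3 arrays), TMP776 (2 arrays) or TMP778 (2 arrays). CCR6 is a chemokine receptor carried by Th17 cells of the blood. The other 3 arrays held CCR6- memory cells at 20 h and CCR6+ and CCR6- memory cells at 16 h, with 1 array each. The compounds were given at 0.2 µM and the vehicle at 0.1% v/v. The labels do not say whether arrays of a group came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

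CCR6, the receptor sorted on, and the Th17 genes set 1 vehicle array of the memory cells apart from its label. At 20 h, CCR6 stood at a log2 intensity of 7.39 and 6.34 in CCR6+ vehicle arrays 1 and 2, and at 4.75 in the CCR6- array. In the array labelled CCR6+ vehicle 3 it stood at 3.69. IL17A was 10.61 and 9.91 in arrays 1 and 2, 6.28 in the array labelled CCR6+ vehicle 3 and 6.16 in the CCR6- array. IL23R, a receptor subunit that sustains Th17 cells, read 8.90, 8.46, 6.30 and 6.39 in the same order, and the mean of the 15 tested Th17 signature genes read 8.50, 7.86, 5.80 and 6.01. At 16 h, CCR6 was 7.59 in the CCR6+ and 2.86 in the CCR6- array. Memory comparisons are therefore given over the groups as labelled and within replicate numbers 1 and 2, where that array has no weight.

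**Figure D1:**
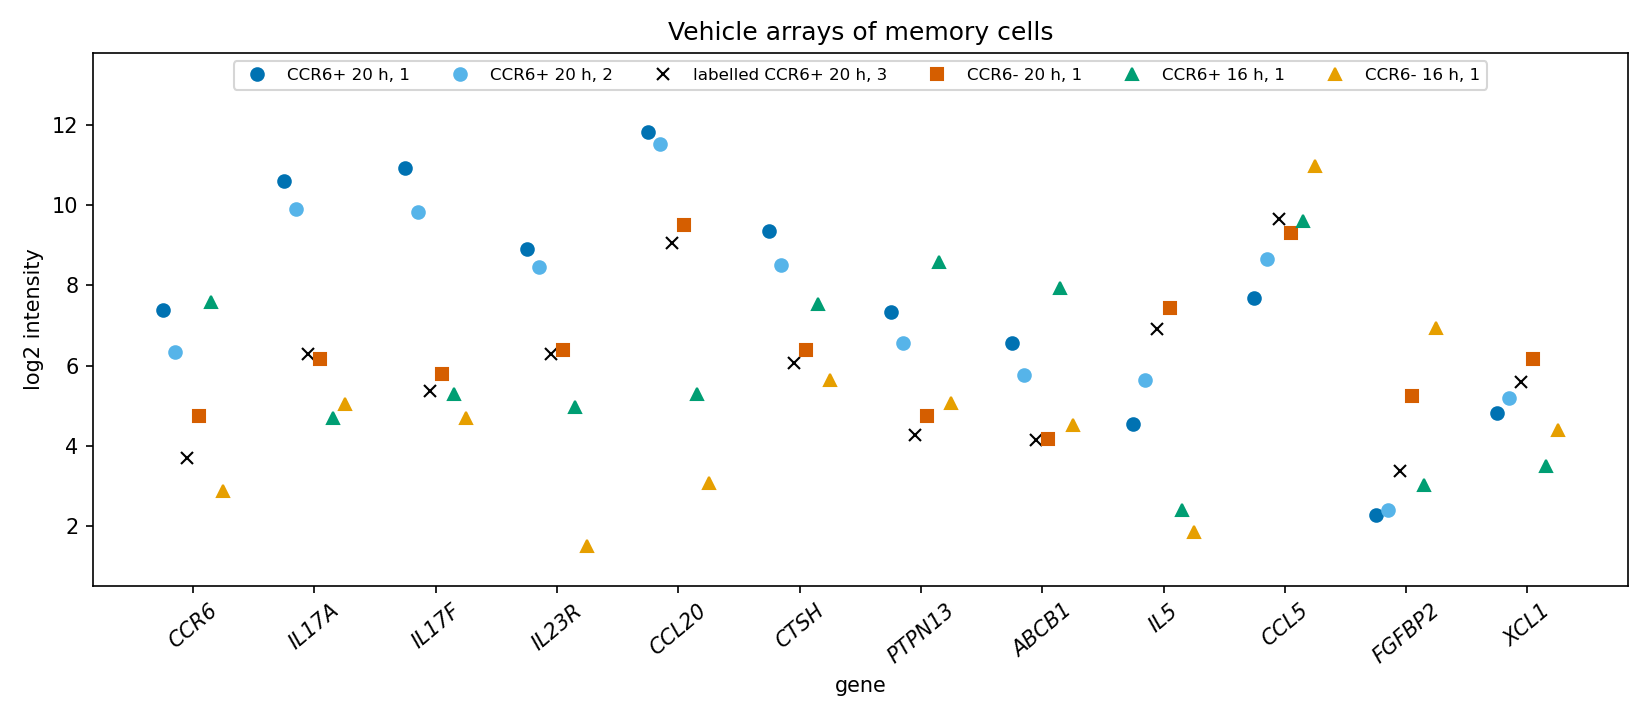
Log2 intensity (vertical axis) of 12 genes (horizontal axis) in the 6 vehicle arrays of memory cells, 1 point per array. In the array labelled CCR6+ vehicle 3 (crosses), CCR6 stood at 3.69 and IL17A at 6.28, near the CCR6- array of 20 h and below the other two CCR6+ arrays of 20 h.

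Naive cells grown with TMP778 had lower mRNA levels of Th17 cytokine and receptor genes than cells grown with DMSO. IL17A averaged an intensity of 132 (log2 7.05 ± 0.06 SD, n = 2) with DMSO and 55.6 (log2 5.80 ± 0.43 SD, n = 2) with TMP778, a log2 difference of -1.25 (SE 0.18, 95% interval -1.66 to -0.84) with the replicate number as a block. Of the 15 Th17 signature genes, 12 were lower in the mean, and 6 fell in limma with the block when adjusted over the list alone, against 0 over all genes tested. These 6 were IL17A (adjusted p = 0.00126), CCR6 with -1.06 (SE 0.16), CTSH, which encodes the lysosomal protease cathepsin H, with -0.82 (SE 0.09), the cytokine gene IL26 with -0.99 (SE 0.29), IL17F with -0.65 (SE 0.17), and CCL20, the ligand of CCR6, with -0.55 (SE 0.11). IL22 read -0.64 (SE 0.37) and IL23R -0.32 (SE 0.14) without passing, and RORA, a nuclear receptor gene, read -0.07. The list mean was -0.39 (95% interval -0.74 to -0.045), at -0.60 within number 1 and -0.19 within number 2. Its camera adjusted p was 0.115 over the group means, 9.26e-06 with the block, and 0.512 with the block and an estimated correlation.

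Other gene lists of the naive cells shifted under TMP778 as well. The 16 interferon response genes averaged 0.18 (camera adjusted p = 6.28e-05 with the block, 0.512 with an estimated correlation and 0.069 over the group means), although number 1 gave 0.35 and number 2 gave 0.02. XAF1, an interferon-induced gene, was the 1 member that rose when adjusted over the list alone, with 0.54, against 0 over all genes. The 15 circadian clock genes averaged -0.12 (camera adjusted p = 0.0296 with the block, 0.638 with an estimated correlation and 0.069 over the group means), at -0.21 within number 1 and -0.04 within number 2. Of these, NR1D1, a clock repressor, fell by 0.42 and BMAL1, a core clock activator, fell by 0.41 over the list alone, and 0 did over all genes. Among T cell activation genes, NR4A3 (0.33), NR4A2 (0.44) and TNFRSF9 (0.26) rose over the list alone and 0 did over all genes. The 8 Th17 targets named in mouse work averaged -0.46 (camera adjusted p = 1.01e-05 with the block, 0.512 with an estimated correlation), at -0.60 within number 1 and -0.33 within number 2, and 4 fell over the list alone. Over all genes limma called 0 in either fit, with 83 at an unadjusted p under 0.05 over the group means and 502 with the block, where chance gives 614. The largest differences at an unadjusted p under 0.01, none of which passed, included the non-coding PRDX6-AS1 with -1.33, CLC with 0.71, CD93 with 0.65, CCL2 with 0.64, PRDM8 with 0.64 and HIC1 with 0.59.

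TMP776 left the Th17 genes of naive cells within the replicate error of DMSO, apart from CTSH. IL17A averaged 133 in intensity with TMP776 against 132 with DMSO, and its log2 difference had a 95% interval from -0.40 to 0.42. The Th17 signature averaged -0.04 (95% interval -0.39 to 0.31), with a camera adjusted p of 0.922 over the group means and 0.937 with the block. CTSH was the 1 gene of the 15 that fell over the list alone, with -0.50 (limma adjusted p = 0.00901), against 0 over all genes. limma called 0 genes in either fit, with 343 at an unadjusted p under 0.05 over the group means and 1368 with the block. SIRT4, a mitochondrial sirtuin gene, read -0.71 (SE 0.06, limma adjusted p = 0.121 with the block). VAV3 read -0.58, TMEM82 0.82, DEFB124 0.81 and MIR181C 0.94, and none passed.

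Set directly against each other in naive cells, at the same dose and time, the 2 compounds differed in the Th17 genes. IL17A was lower with TMP778 than with TMP776 by a log2 difference of -1.26 (SE 0.18, 95% interval -1.67 to -0.85), and CCR6 by -0.97 (SE 0.16, 95% interval -1.35 to -0.59). With the block, 5 of 15 Th17 signature genes were lower in limma when adjusted over the list alone, IL17A (adjusted p = 0.0024), CCR6, IL26 (-1.09), CCL20 (-0.48) and CTSH (-0.32), and 0 over all genes. The list averaged -0.35 (95% interval -0.70 to -0.0042), with a camera adjusted p of 0.204 over the group means, 2.05e-06 with the block and 0.553 with the block and an estimated correlation. It read -0.56 within number 1 and -0.15 within number 2. The interferon genes averaged 0.27 (95% interval 0.02 to 0.53, camera adjusted p = 6.02e-04 with the block, 0.553 with an estimated correlation and 0.285 over the group means). IFI44 (0.76), XAF1 (0.41) and OAS1 (0.37) were higher over the list alone, and 0 over all genes. The 10 naive and central memory markers were all positive with a mean of 0.13 (camera adjusted p = 0.0401 with the block, 0.553 with an estimated correlation), at 0.037 within number 1 and 0.22 within number 2, and 0 members passed. limma called 0 genes in either fit, with 120 and 867 at an unadjusted p under 0.05, and among those that did not pass were ADAM23 with 0.73, CXCL13 with 0.63 and CD38 with 0.59.

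**Figure D2:**
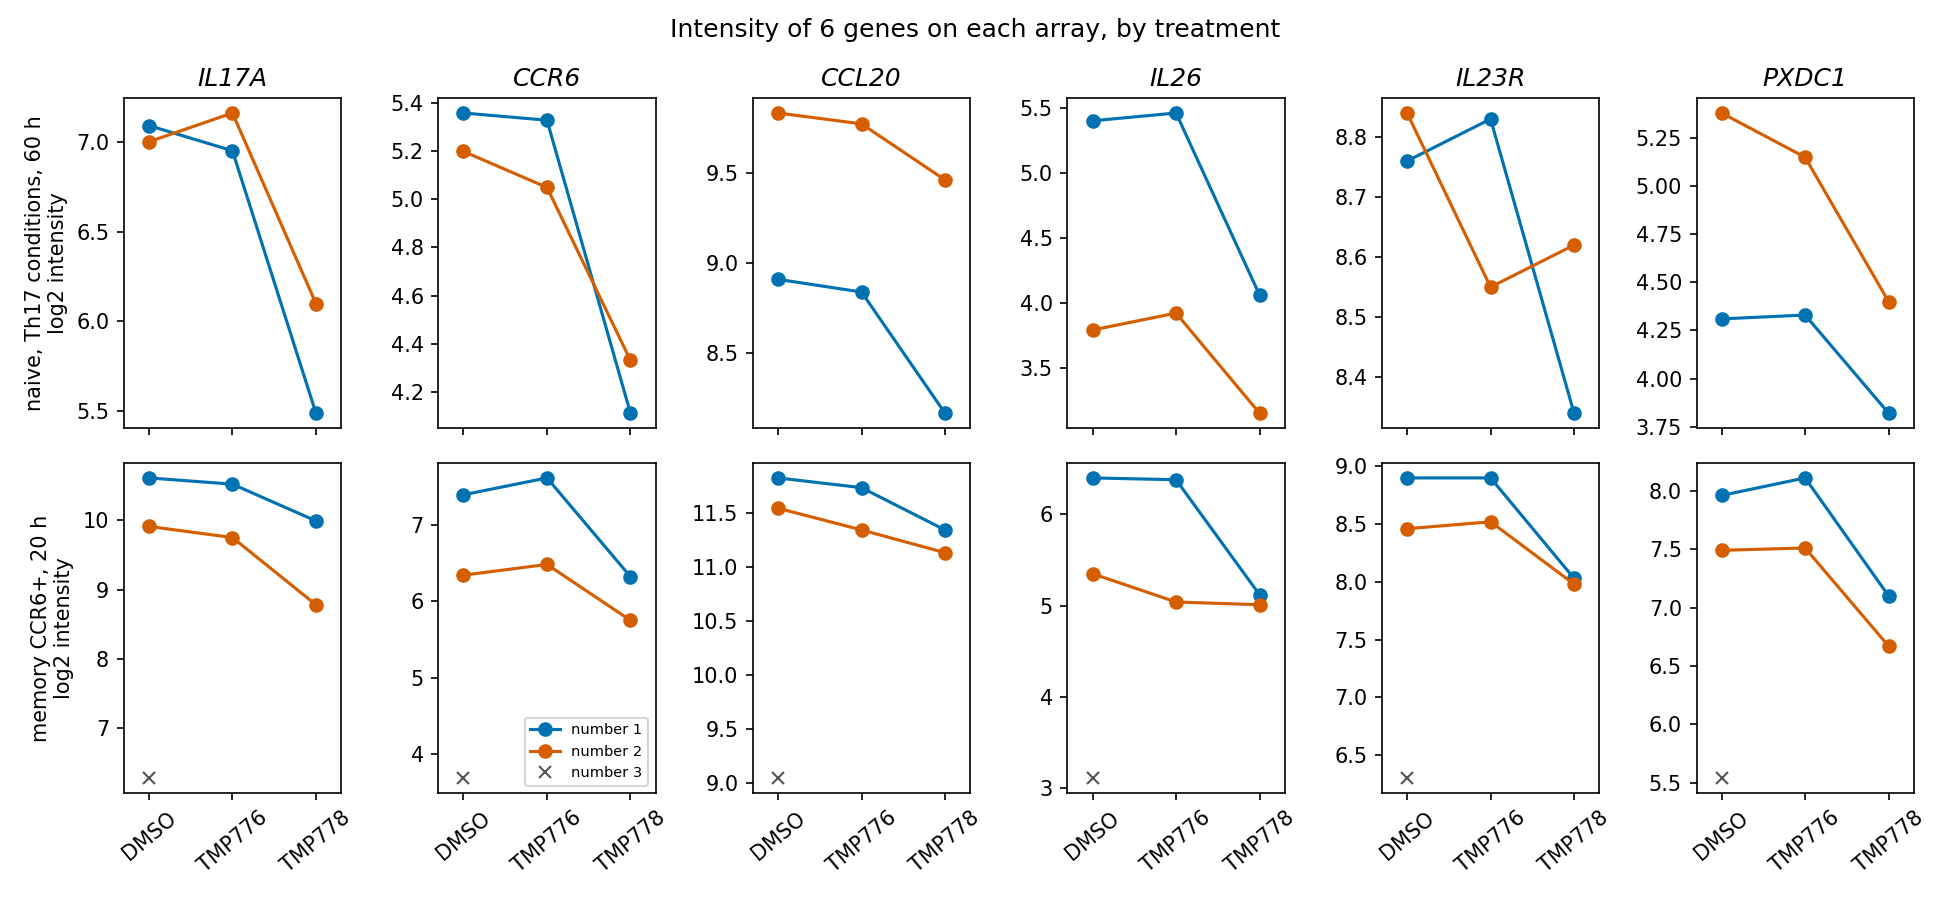
Log2 intensity (vertical axes) of IL17A, CCR6, CCL20, IL26, IL23R and PXDC1 by treatment in naive (upper) and memory (lower) cells, 1 point per array, lines joining arrays of the same number within a system, each panel on its own scale. In naive cells IL17A averaged 7.05 with DMSO, 7.06 with TMP776 and 5.80 with TMP778, and in memory cells the array labelled CCR6+ vehicle 3 lay at 6.28, apart from the other two vehicle arrays.

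In CCR6+ memory cells stimulated for 20 h, the direction of the Th17 genes under TMP778 depended on the array labelled CCR6+ vehicle 3. Within replicate numbers 1 and 2, IL17A was lower with TMP778 than with DMSO by a log2 difference of -0.87 (SE 0.18, 95% interval -1.29 to -0.46), CCR6 by -0.83 (SE 0.16) and IL23R by -0.68 (SE 0.14). With the block, 8 of 15 Th17 signature genes fell in limma when adjusted over the list alone and 0 over all genes. They were IL17A, CCR6 and IL23R (each with an adjusted p of 0.0104), CCL20 (-0.45), CTSH (-0.37), KLRB1 (-0.31), which encodes the receptor CD161, ADAM12 (-0.55) and IL26 (-0.81). IL17F read -0.27 (SE 0.17) and IL22 -0.52, and neither passed. The list averaged -0.38 (95% interval -0.72 to -0.027), at -0.42 within number 1 and -0.33 within number 2, with a camera adjusted p of 4.54e-05, or 0.520 with an estimated correlation. Over the groups as labelled, IL17A averaged 9.38 ± 0.85 (SD, n = 2) with TMP778 and 8.93 ± 2.32 (SD, n = 3) with DMSO. The list mean was then 0.42 (camera adjusted p = 3.14e-04, or 0.452 with an estimated correlation), the opposite direction, and 0 members passed over the list alone. This mean became 0.98 without vehicle array 1, 0.66 without vehicle array 2, 0.69 without TMP778 array 2, and 0.14 without TMP778 array 1, where it did not pass.

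Cell cycle and interferon genes of memory cells also differed between TMP778 and DMSO. The 18 cell cycle genes averaged -0.20 with 17 of them negative (camera adjusted p = 0.00126 with the block, or 0.938 with an estimated correlation), at -0.31 within number 1 and -0.09 within number 2. Over the groups as labelled it averaged -0.23 (2.94e-06, or 0.452 with an estimated correlation). AURKB, a mitotic kinase gene, with -0.59 and MCM2, a DNA replication gene, with -0.32 fell over the list alone, and 0 over all genes. The interferon genes averaged 0.20 with the block (camera adjusted p = 1.81e-04, or 0.520 with an estimated correlation) and 0.32 over the groups as labelled (0.00279, or 0.452), where the array labelled CCR6+ vehicle 3 has weight. With the block, RSAD2 (0.64) and IFIT3 (0.62) rose over the list alone, with 0 over all genes. NR1D1 fell by 0.32 over the clock list alone, with 0 over all genes. The Th17 targets named in mouse work averaged -0.36 with the block (camera adjusted p = 0.00569, or 0.520 with an estimated correlation) and 0.39 over the groups as labelled (0.0138, or 0.452). In the groups as labelled, the Th2 list (-0.32, camera adjusted p = 0.0289), the CD8 T and NK cell markers (-0.24, 0.0344) and the innate-like T cell markers (0.33, 0.0289) passed too, but not with an estimated correlation (0.452 for each), and with the block they read -0.06, -0.11 and -0.07 and did not. limma called 0 genes in either fit, with 53 at an unadjusted p under 0.05 over the groups as labelled and 738 with the block. PXDC1 with -0.84, CD160, a receptor of cytotoxic lymphocytes, with -0.76, and AKR1C2 with -0.95 were among the largest that did not pass.

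TMP776 showed no detectable difference from DMSO in the Th17 genes of memory cells once arrays were compared within numbers. IL17A then read -0.13 (95% interval -0.54 to 0.28), CCR6 0.18 (95% interval -0.20 to 0.56) and the Th17 signature -0.05 (95% interval -0.40 to 0.30, camera adjusted p = 0.870), with 0 members passing over the list alone. Over the groups as labelled the Th2 list averaged -0.38 (camera adjusted p = 0.0239) and the innate-like markers 0.46 (0.0052). Neither passed with an estimated correlation (0.465 for both), and with the block they read -0.12 and 0.06 without passing. The Th17 signature averaged 0.75 as labelled (camera adjusted p = 1.69e-07, or 0.465 with an estimated correlation), but this became 1.30 without vehicle array 1 and 0.39 without TMP776 array 1, where it did not pass. limma called 0 genes in either fit, with 97 and 592 at an unadjusted p under 0.05. XCL1, a chemokine gene, read -0.58 and CXCL13, another, -0.70, and neither passed.

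Between the 2 compounds in memory cells, which does not involve the vehicle arrays, TMP778 gave the lower Th17 levels. With the block, CCR6 differed by -1.01 (SE 0.16, 95% interval -1.39 to -0.63), IL17A by -0.75 (SE 0.18, 95% interval -1.16 to -0.33), IL23R by -0.71 (SE 0.14, 95% interval -1.04 to -0.37) and CTSH by -0.41. These 4 of 15 Th17 signature genes were lower in limma over the list alone (adjusted p = 0.00579 for CCR6 and 0.0132 for IL17A) and 0 over all genes. The list averaged -0.33 (95% interval -0.68 to 0.02), with a camera adjusted p of 0.155 over the group means, 3.63e-07 with the block and 0.383 with the block and an estimated correlation. In numbers 1 and 2 the list mean read 8.49 and 7.775 with TMP776 and 8.08 and 7.53 with TMP778, lower with TMP778 in both. Over the group means the list became 0.03 without TMP776 array 1 and -0.05 without TMP778 array 2. It passed without TMP776 array 2 (-0.69) or TMP778 array 1 (-0.60). Those fits ignore the pairing, so with 1 array gone the gap between numbers 1 and 2 enters the difference. The cell cycle genes averaged -0.18 (camera adjusted p = 0.0105 with the block, 0.616 with an estimated correlation), at -0.40 within number 1 and 0.03 within number 2. AURKB (-0.85), MKI67 (-0.70), which encodes the proliferation marker Ki-67, and CCNA2 (-0.41) were lower over the list alone, and 0 over all genes. The interferon genes averaged 0.22 (camera adjusted p = 3.63e-07 with the block, 0.383 with an estimated correlation), and RSAD2 (0.68) was higher over the list alone. The clock list (-0.10, camera adjusted p = 0.0314 with the block, 0.565 with an estimated correlation) and the Th1 list (0.06, 0.0499 and 0.565) passed with 0 members doing so. Within numbers 1 and 2 the clock list read -0.19 and -0.015, and the Th1 list 0.0045 and 0.11. limma called 0 genes in either fit, with 43 and 349 at an unadjusted p under 0.05, and PXDC1 read -0.93 and the Th2 cytokine gene IL5 read 0.52 without passing.

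**Figure D3:**
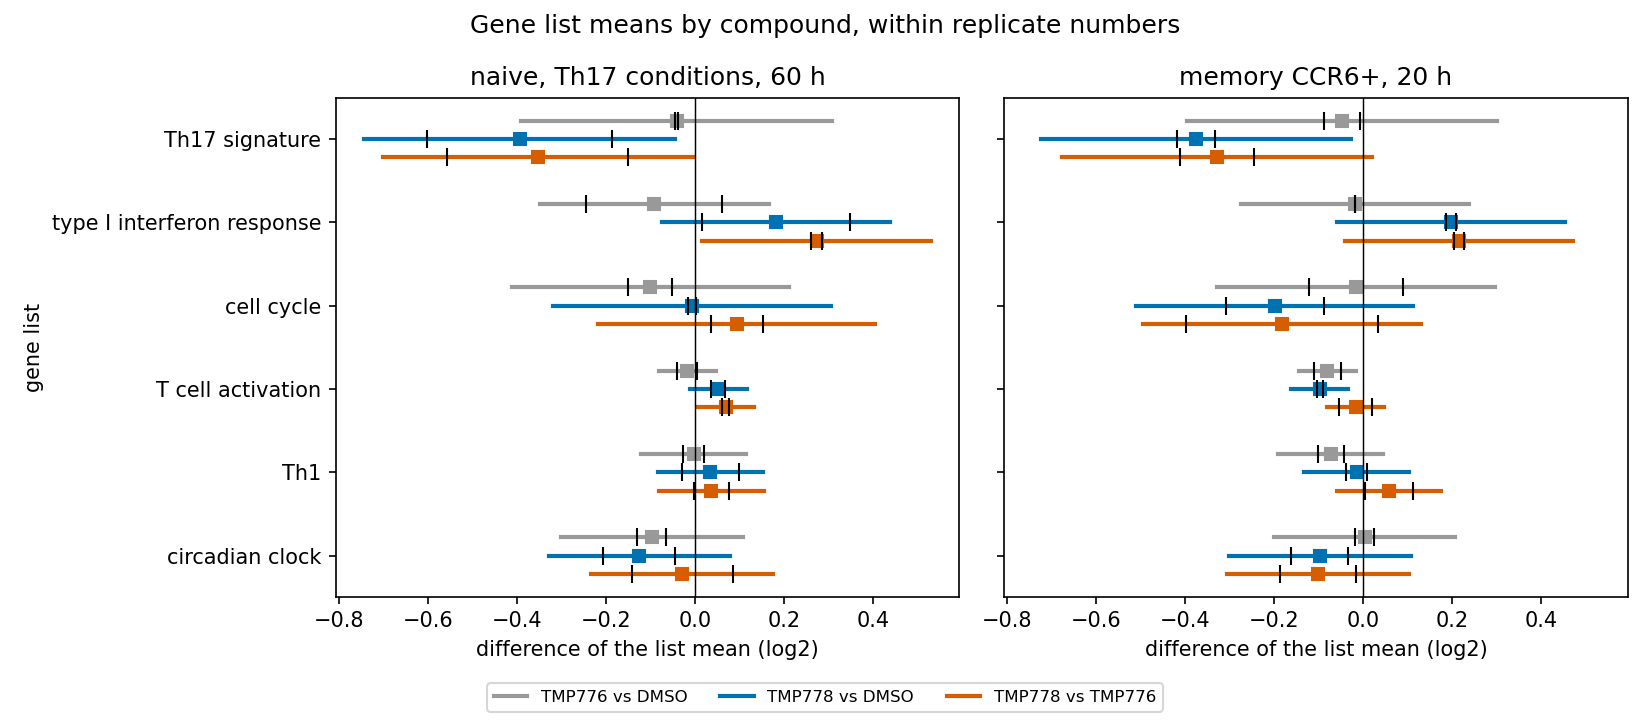
Mean log2 difference of 6 gene lists (vertical axis) for 3 comparisons of compounds within replicate numbers, in naive (left) and memory (right) cells, with 95% intervals as bars and the values of numbers 1 and 2 as ticks. The Th17 signature lies at -0.39 for TMP778 and -0.04 for TMP776 against DMSO in naive cells, and at -0.38 and -0.05 in memory cells.

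Whether the effect of TMP778 differed between naive and memory cells also turned on the array labelled CCR6+ vehicle 3. With the block, the Th17 signature differed by -0.02 between the systems (naive minus memory, 95% interval -0.51 to 0.48, camera adjusted p = 0.644). As labelled, the groups gave a difference of -0.81 (camera adjusted p = 3.44e-05, or 0.490 with an estimated correlation), which became -1.37 without memory vehicle array 1 and -0.54 without memory TMP778 array 1. limma called 0 genes for this difference in either fit, with 50 and 431 at an unadjusted p under 0.05. Across all 12273 genes, which are not independent replicates, the effects of TMP778 in the 2 systems correlated with r = 0.151 (Spearman's rho 0.135) within numbers and 0.0686 over the groups as labelled. Within numbers, 34 genes had an unadjusted p under 0.05 and lower values in both systems, from 270 in naive and 535 in memory cells, where independent lists share 11.8. Among them were IL17A, CCR6, IL26, CTSH, CCL20, NR1D1, PXDC1 and SIRT4 (-0.55 and -0.31). Chosen after their values were seen were EGLN3, a hypoxia-induced oxygen sensor gene (-0.44 and -0.62), TIMP1 (-0.53 and -0.37) and S100A4 (-0.50 and -0.26). The overlap is against DMSO alone and does not part falls that TMP776 shared, as SIRT4 and CTSH also read lower with TMP776 in naive cells. Higher in both were 9 genes, from 232 and 203, where independent lists share 3.84, and they included ABCG1, a cholesterol transporter gene (0.27 and 0.32).

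The effects of TMP778 and TMP776 against DMSO share their vehicle arrays and so correlate by construction. In naive cells they correlated across genes with r = 0.587 (Spearman's rho 0.505), against 0.501 in simulations of unchanged groups, and 69.2% of genes had the same sign, against 66.7%. The covariance was 0.0139, against a simulated 0.0303 over the group means and 0.00693 with the block. In memory cells within numbers, r was 0.637 (rho 0.619), against 0.499 simulated, and the covariance 0.0121, against 0.00689. For the groups as labelled r was 0.646, against 0.402, and the covariance 0.0124, against 0.0202. limma called 0 genes for either compound, so 0 were shared. Each vehicle group held too few arrays to be split, and part of any excess may come from the shared vehicle arrays.

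CCR6+ memory cells differed from CCR6- memory cells in Th17 genes, averaged over 20 h and 16 h. CCR6 itself (3.65) was sorted on and is no finding, but it is counted in the means, calls and tests of both Th17 lists below. With the block, IL23R (2.96), IL17F (2.95), the phosphatase gene PTPN13 (3.03), the drug efflux pump gene ABCB1 (2.88), CTSH (2.42), CCL20 (2.27, SE 0.10) and IL17A (2.10, SE 0.17, limma adjusted p = 0.00111) were higher in CCR6+ cells. All 15 Th17 signature genes rose over the list alone and 14 over all genes, with a mean of 2.10 (95% interval 1.77 to 2.44, camera adjusted p = 8.46e-27, or 0.0418 with an estimated correlation), and IL26 (0.87) was the exception over all genes. The times were then taken singly, chosen after the data were seen, and are given as values without a test, since each holds 1 CCR6- array. The 16 h arrays had low T cell activation genes, with list means of 5.54 (CCR6+) and 5.61 (CCR6-) against 9.10 to 9.34 in memory arrays of 20 h. At 20 h the Th17 list averaged 2.49 with 15 of 15 genes positive, and at 16 h 1.71 with 13 of 15. IL17A differed by 4.55 at 20 h and -0.36 at 16 h, where it was low in the CCR6+ (4.69) and the CCR6- array (5.05). IL17F read 5.32 and 0.59. IL26 and IL22 differed by 2.58 and 3.17 at 20 h, and at 16 h both lay under the filter level of 4.5 in both arrays. PTPN13 (2.54 and 3.52), CTSH (2.96 and 1.89), ABCB1 (2.35 and 3.42), IL23R (2.43 and 3.48) and CCL20 (2.33 and 2.20) were higher at both times. The size of some differences rests on dim values under that level, such as IL23R (1.49), CCL20 (3.08) and CCR6 (2.86) in the CCR6- array of 16 h and ABCB1 (4.17) in that of 20 h. The Th17 targets named in mouse work averaged 1.96 (camera adjusted p = 3.19e-13, or 0.0418 with an estimated correlation), 7 of 8 rising on both counts, at 2.39 at 20 h and 1.54 at 16 h, where 6 of 8 were positive. Outside the lists, B3GALT2 (3.89), ELOVL4 (3.19) and the histamine receptor gene HRH4 (2.94) were also higher, from dim CCR6- values at 20 h of 3.90, 4.10 and 4.77. FGFBP2, a gene of cytotoxic lymphocytes, was lower in CCR6+ cells with -3.44 (limma adjusted p = 3.67e-05), with dim values in the CCR6+ arrays (2.26 and 2.39 in arrays 1 and 2 of 20 h). Other lower genes were GZMK (-2.46), which encodes granzyme K, FCRL3 (-2.28), ST8SIA1 (-1.82), the Th2 cytokine gene IL13 (-1.72), EOMES (-1.68), AOAH (-1.64), TIGIT (-1.62), PECAM1 (-1.62) and FHIT (-1.60). Of these, AOAH (-0.59 at 20 h and -2.69 at 16 h), PECAM1 (-0.98 and -2.25) and FHIT (-0.98 and -2.21) rested mostly on the 16 h arrays. Values under the filter level make the size of some falls uncertain, as in CCR6+ array 1 of 20 h for GZMK (2.37), FCRL3 (3.27), PECAM1 (3.34) and FHIT (2.34).

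Other T helper and metabolic gene groups of these cells differed with the block, with the values of single times given without a test. The 8 Th2 genes averaged -0.84 (camera adjusted p = 2.99e-07, or 0.0418 with an estimated correlation), with 6 lower over the list alone and 4 over all genes, IL13, IL17RB (-1.39), IL4 (-1.28) and IL5 (-1.16). The Th2 list averaged -1.70 at 20 h and 0.014 at 16 h, where the T cell activation genes were low and these cytokines dim in the CCR6+ and CCR6- array, IL13 at 3.57 and 3.84, IL4 at 2.35 and 2.53 and IL5 at 2.40 and 1.85. At 20 h, IL13 differed by -3.17, IL17RB by -2.98, IL4 by -2.38 and IL5 by -2.87, against 1 CCR6- array. The 5 innate-like T cell markers averaged 0.97 (camera adjusted p = 6.12e-06, or 0.0418 with an estimated correlation), 4 higher over the list alone and 3 over all genes, among them SLC4A10 (2.02) and DPP4 (1.47), both marks of mucosal-associated invariant T cells. It read 1.10 at 20 h and 0.85 at 16 h, with dim SLC4A10 in the CCR6- arrays (3.74 and 3.60). Cholesterol genes averaged 0.26 (camera adjusted p = 2.61e-07, or 0.225 with an estimated correlation), 10 of 17 higher over the list alone and 4 over all genes, for example FDPS (0.53) and HMGCS1 (0.45), and read 0.37 at 20 h and 0.14 at 16 h. Clock genes averaged 0.24 (0.00242, or 0.474 with an estimated correlation), with PER3 (0.76) and NR1D1 (0.57) among 6 over the list alone and 4 over all genes. The clock list read 0.16 at 20 h and 0.32 at 16 h, and NR1D1 0.06 and 1.07. Tfh genes averaged -0.27 (0.00364, or 0.485 with an estimated correlation), with CXCR5 (-1.24), TOX (-0.64) and BTLA (-0.31) lower on both counts. The Tfh list read -0.33 at 20 h and -0.21 at 16 h, BTLA -0.80 and 0.19, and TOX -0.26 and -1.01. The Th1 list did not pass (-0.25, camera adjusted p = 0.0676), as CCL5 (-1.50), EOMES, PRF1 (-0.90) and IFNG (-0.81) were lower and IL18R1 (0.84) and IL18RAP (0.70) higher. Of these, IL18R1 (0.30 at 20 h and 1.38 at 16 h) and IFNG (-0.44 and -1.19) rested mostly on the 16 h arrays. IFNG was dim in the CCR6+ array of 16 h (3.58). Interferon genes averaged 0.24 (0.0446, or 0.485 with an estimated correlation), with IFI44L (1.12), IFIT2 (0.97) and RSAD2 (0.68) higher over all genes. That list read 0.30 at 20 h and 0.18 at 16 h, IFI44L 0.33 and 1.91, IFIT2 1.78 and 0.15, and RSAD2 1.36 and 0.012. The list mean at 20 h was 6.17 and 5.65 in CCR6+ vehicle arrays 1 and 2, 5.55 in that labelled 3 and 5.87 in the CCR6- array. The 0.30 at 20 h therefore rests on the pairing of the CCR6- array with number 1.

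The number of genes called between CCR6+ and CCR6- cells rested on the fit and on 1 array. limma called 630 genes with the replicate block (371 higher, 259 lower), 0 over the groups as labelled (593 at an unadjusted p under 0.05) and 20 without the array labelled CCR6+ vehicle 3. With the groups as labelled, IL17A read 1.21 (limma adjusted p = 1.00) and the Th17 signature 1.54 (camera adjusted p = 9.84e-16, or 0.205 with an estimated correlation), with 8 of 15 genes higher over the list alone. The CCR6- cells had 1 array at each time, which the fit assumes to vary like the other groups. The block also takes these arrays and the CCR6+ array of 16 h as number 1 by label. The 630 calls rest on that unchecked pairing. Across genes the CCR6- array of 20 h correlated at 0.987 with CCR6+ vehicle array 1 of 20 h and at 0.982 with array 2. For the 16 h arrays these were 0.796 and 0.807 (CCR6+) and 0.788 and 0.802 (CCR6-), nearer number 2. The 16 h arrays stood apart from those of 20 h, with correlations of 0.788 to 0.813 across genes.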

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

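Of the tests in this part, that on the wider gene set for the array labelled CCR6+ vehicle 3 was chosen only after the result was seen. The TMP776 gene count with both the block and quantile normalization was added after the data were seen, and what it would show was written down before its result.

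The effect of TMP778 against DMSO differed between naive and memory cells in some gene lists, by camera tests of the difference itself (naive minus memory). Over the groups as labelled, the Th17 signature differed by -0.81 (camera adjusted p = 3.44e-05) and the Th17 targets named in mouse work by -0.86 (0.0067), and with the replicate block these became -0.02 (0.644) and -0.10 (0.348). The cell cycle list differed by 0.22 over the groups as labelled (6.03e-04) and by 0.19 with the block (0.0138, 17 of 18 genes positive), although the 95% interval of its mean ran from -0.25 to 0.63. The T cell activation list was flagged only with the block, where it differed by 0.15 (0.0138, 95% interval 0.06 to 0.24, 11 of 13 genes positive), from 0.05 in naive and -0.10 in memory cells. NR4A2, an immediate early nuclear receptor gene, was the 1 member past the threshold over that list alone, with 0.74, and 0 were over all genes. With an estimated correlation, none of these lists passed, with adjusted p = 0.490 over the groups as labelled and 0.723 (activation) and 0.950 (cell cycle) with the block.

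The array labelled CCR6+ vehicle 3 had low CCR6 and low Th17 genes, and 3 explanations were weighed. A weaker stimulation was to show as T cell activation genes below the other 6 CCR6+ arrays of 20 h. These ran from 9.10 to 9.23, and the array read 9.14, within that range. The values under 9.14 came from arrays with a compound, and vehicle arrays 1 and 2 read 9.23 and 9.21. Slightly weaker stimulation of this array therefore stays open. That it held CCR6- cells stayed open: on a scale from the CCR6- array (0) to the CCR6+ arrays (1) of 20 h, the median position was 0.07 over 5 genes higher and 0.288 over 2 genes lower in CCR6+ cells, and in the wider set of 32 and 14 genes it was 0.065 and 0.256. Cells from another source, with neither number 1 nor number 2, stayed open too. Over 60 genes that part the numbers, the difference of this array from the CCR6- array of number 1 followed that of number 2 from number 1 with a slope of 0.78. Across all tested genes the array lay nearer number 2. Its correlation was 0.993 with vehicle array 2, 0.987 with the CCR6- array and 0.980 with vehicle array 1. Its deviation from its group went with those of number 2 under TMP776 (r = 0.552) and TMP778 (0.516). Of the 7 genes, HRH4 (7.43 and 6.64 in arrays 1 and 2, 3.96 in this array, 4.77 in the CCR6- array) lay with the CCR6- array and FGFBP2 (2.26, 2.39, 3.36 and 5.24) nearer the CCR6+ arrays, and a mislabelled sample and another source may both hold.

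In naive cells, TMP776 gave more genes at an unadjusted p under 0.05 than TMP778 with the block, 1368 against 502, although the mean of its Th17 signature was not detectably different from DMSO and limma called 0 genes for either. Most of the 1368 genes were dim, as a share of 0.2405 of them lay among the brighter genes when all tested genes were parted at the median brightness. That share was not taken for the 502 genes of TMP778. Whether dim probes account for part of the excess therefore cannot be told. The intensity distribution of single arrays cannot be told apart from a treatment effect, since quantile normalization lowered the count only to 1115, against 537 for TMP778. The TMP776 count leaned on array 2: over the group means it was 343, 916 without TMP776 array 1 and 195 without array 2. The SD of TMP776 minus DMSO across genes was 0.191 in number 1 and 0.269 in number 2, with r = 0.187 between them. For TMP778 minus DMSO the SD was 0.216 and 0.141, with r = 0.058. Uneven numbers therefore do not set TMP776 apart, and its differences were more alike between numbers than those of TMP778. An effect of TMP776 itself stays open and was not tested separately.

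In memory cells the cell cycle genes were lowest under TMP778 in the mean of both numbers. A weaker stimulation of those cultures cannot be told apart, as the T cell activation list under TMP778 minus TMP776 was -0.05 within number 1 and 0.021 within number 2, with differences too small to decide. The cell cycle list read -0.40 and 0.03 in the same order. Against DMSO the activation list under TMP778 read -0.10 and -0.09 and the cell cycle list -0.31 and -0.09, so a lower activation level stays open. An effect of TMP778 on proliferation remains a candidate explanation, untested here.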

How the results depend on the processing

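Alternatives added after the data were seen are the replicate block joined with an estimated correlation, the Th17 list without CCR6, the single time points of the CCR6 comparison with the block or without 1 array, and all settings of the contrast over both systems. Of 304 alternatives of the results that answer a comparison, 258 kept the direction and the side of the threshold. These include 118 gene counts that stayed at 0, and some alternatives could not turn, such as a fold cut added to a count of 0. The 258 are therefore no measure of stability. Of 204 alternatives of named genes 182 did, and 22 reversed, all under the block in memory cells against DMSO. Most of the 182 had no way to turn, so they say little about stability. Dropping the filter leaves the difference of a gene as it was. So does the block in naive cells and between the compounds in memory cells. The gene counts between treatments, and for the difference between systems, were 0 in all 118 alternatives. The number of arrays and the dimness of many probes limit what the calls show. Where no cause is given, the cause was not tested.

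For the Th17 signature in naive cells, TMP778 against DMSO and against TMP776 passed in camera with the stricter filter (-0.60 and -0.46), in fits of the naive arrays alone (-0.39 and -0.35), with the replicate block (-0.39 and -0.35), and with the block and without CCR6 (-0.35 and -0.31), but not with the block and an estimated correlation (adjusted p = 0.512 and 0.553). Leaving out 1 array gave -0.56 to -0.22 and -0.52 to -0.18, and for TMP776 against DMSO -0.078 to -0.0038. In memory cells TMP778 against TMP776 passed with the block (-0.33), with arrays centred (-0.31), and with the block without CCR6 (-0.28), but not with the block and an estimated correlation (0.383), and leaving out 1 array gave -0.69 to 0.031.

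Against DMSO in memory cells the list turned under the replicate block, to -0.38 for TMP778 and -0.048 for TMP776, also with an estimated correlation (-0.38 and -0.048) and without CCR6 (-0.34 and -0.064). By its construction the block takes out the array labelled CCR6+ vehicle 3, and leaving out that array gave the same values. Leaving out 1 array at a time gave -0.38 to 0.98 for TMP778 and -0.048 to 1.30 for TMP776. Without the block but with an estimated correlation, 0.42 and 0.75 no longer passed. The difference between systems was -0.81 and no longer passed with an estimated correlation, and became -0.018 with the block, alone or with an estimated correlation, and -0.0033 without CCR6 too, with -1.37 to -0.018 when 1 array was left out.

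Named genes of memory cells that turned under the block, for TMP778 against DMSO, were IL17A (-0.87), IL17F (-0.27), IL22 (-0.52), IL26 (-0.81), IL23R (-0.68), CCR6 (-0.83), CCL20 (-0.45), KLRB1 (-0.31), CTSH (-0.37), PTPN13 (-0.017), ABCB1 (-0.067), ADAM12 (-0.55), IL17RE (-0.086) and FURIN (-0.030). For TMP776 against DMSO they were IL17A (-0.13), IL17F (-0.090), IL22 (-0.20), IL26 (-0.17), CCL20 (-0.15), KLRB1 (-0.12), ABCB1 (-0.14) and ADAM12 (-0.19).

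For CCR6+ against CCR6- cells, limma called 0 genes over the groups as labelled, 3 with no filter, 3 with all probes, 630 with the replicate block, 357 at 20 h alone with the block, 384 at 16 h alone with the block and 6 at 20 h without the array labelled CCR6+ vehicle 3. The counts at single times have 1 CCR6- array, and at 16 h 1 CCR6+ array too, so their spread is taken from other groups and they say nothing about stability. Leaving out 1 array gave 0 to 20. The Th17 list of 1.54 no longer passed with an estimated correlation, and leaving out 1 array gave 1.27 to 1.94. The block changed no call of the report other than those given there and here.

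For the contrast of TMP778 with the other arrays of its replicate set over both systems, 4 genes passed, against 3 with no filter, 7 with the stricter filter, 2 with quantile normalization, 7 with an intensity trend and robust prior, and 0 to 1 when 1 set was left out, where fewer arrays remain. The call of NR1D1 ended with no filter, and those of NR1D1 and IL17A with quantile normalization. Its Th17 list mean ran from -0.43 to -0.29 over the sets left out.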

Other observations

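The contrast of TMP778 with the other arrays of its replicate set, the split tests of the Th17 and interferon lists, and the single times of the CCR6 comparison, were chosen only after the result was seen. The split test of the gene count was written down before its result.

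Over both culture systems, 4 genes were lower with TMP778 than with DMSO and TMP776 in limma, and 0 were higher. The fit used 12 arrays in 4 replicate sets, each set holding 1 array of DMSO, TMP776 and TMP778 of 1 system and number. The genes were CCR6 with -0.97 (SE 0.09, adjusted p = 0.00651), PXDC1 with -0.78 (SE 0.07, 0.00651), IL17A with -1.03 (SE 0.12, 0.0189) and NR1D1, a circadian repressor, with -0.34 (SE 0.04, 0.0448), each lowest under TMP778 in 4 of 4 sets. At an unadjusted p under 0.05 there were 509 genes, where chance gives 614. The count dropped to 0 without naive set 2 and to 1 without naive set 1, memory set 1 or memory set 2. TMP776 against DMSO gave 1 gene in the same sets, RASGRP3 with -0.45 (limma adjusted p = 0.0437), with 1565 at an unadjusted p under 0.05. Of the 15 Th17 signature genes, 9 were lower over the list alone and 2 over all genes, and of the 8 Th17 targets named in mouse work 5 and 2, with a mean of -0.39.

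Interferon genes moved the other way in the same contrast. The list averaged 0.22 and was highest under TMP778 in 4 of 4 sets. In naive set 2 it barely exceeded DMSO, with 5.29 under TMP778, 5.27 under DMSO and 5.02 under TMP776. In limma 7 of 16 genes were higher over the list alone and 0 over all genes, among them IFI44 (0.47), RSAD2 (0.44), USP18 (0.42), IFIT2 (0.42) and XAF1 (0.33). ABCG1, a cholesterol efflux transporter and LXR target, was higher over its list alone with 0.27 (limma adjusted p = 0.00585) and highest under TMP778 in 4 of 4 sets. The LXR targets did not rise as a list, with 5 of 7 negative and a mean of 0.0065. The clock list averaged -0.09, and NR1D1 and BMAL1 (-0.27) were its 2 genes lower over the list alone.

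Exact picks of 1 array from each of the 4 sets bear on chance. For the Th17 list, 1 of 81 picks gave a mean as low as -0.36, the real one, and the lowest of the others was -0.31. For the genes called, 1 of 81 picks gave as many as 4, and the highest of the others was 0. For the interferon list, 1 of 81 picks gave a mean as high as 0.22, and the highest of the others was 0.21. For the gene count this share is under 0.05, but the contrast was chosen after lower Th17 genes had been seen in both systems, so the picks are no independent test of chance. The two-sided exact p of the Th17, Th17 target and interferon list means was 0.0247, the smallest that 81 picks can give. After adjustment over 22 lists it was 0.181, which does not pass. With so few picks, a list can pass this adjustment only if many lists share the smallest p. Not passing was therefore nearly fixed in advance and does not count against these lists, and chance is not excluded for them.

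The other lists of the same contrast did not pass either, in exact tests adjusted over the 22 lists, where the number of picks left little room to pass. The innate-like T cell markers averaged -0.09 (adjusted p = 0.272), the clock list -0.09 (0.435), other Th17 transcription factors -0.03 (0.698), AHR and NRF2 targets 0.08 (0.698, 8 of 8 genes positive), Th1 genes 0.03 (0.785) and CD8 T and NK cell markers -0.08 (0.785). Th2 genes (0.03), the cell cycle (-0.07), cholesterol genes (-0.02) and glycolysis genes (-0.0093) had an adjusted p of 0.892. Treg (-0.01), Tfh (0.01), T cell activation (0.0020), naive and central memory markers (0.02), LXR targets (0.0065), ER stress (-0.0082) and B cell markers (0.02) had 0.914. Monocyte markers averaged -0.04 (0.905), with TMP776 above DMSO by 0.16, and the 1 tested platelet gene 0.24 (0.815).

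Between CCR6+ and CCR6- memory cells, the other lists gave these camera means with the block. The cell cycle list averaged -0.14 (adjusted p = 0.0303, or 0.512 with an estimated correlation), with 4 genes lower over the list alone and 0 over all genes. It read -0.23 at 20 h and -0.05 at 16 h, values without a test as each time holds 1 CCR6- array. Glycolysis and hypoxia genes averaged 0.10 (0.0485, or 0.485), with PFKFB3 (0.31) higher on both counts, and the list read 0.12 at 20 h and 0.07 at 16 h. LXR targets averaged 0.18 (0.0676), ER stress genes 0.11 (0.0967), AHR and NRF2 targets 0.10 (0.240), other Th17 transcription factors 0.03 (0.451), Treg genes -0.21 (0.451), T cell activation genes -0.09 (0.270) and naive markers -0.20 (0.116). Markers of B cells (0.15, 0.256), monocytes (0.06, 0.808) and CD8 T and NK cells (-0.35, 0.113) did not pass, and the last read 0.16 at 20 h and -0.86 at 16 h.

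The 16 h arrays of memory cells, which the labels give as stimulated, had low T cell activation genes. The list averaged 5.54 in the CCR6+ and 5.61 in the CCR6- array, against 9.10 to 9.34 over the 8 memory arrays of 20 h. IL17A stood at 4.69 and 5.05, CCL20 at 5.28 and 3.08, and the cell cycle genes averaged 4.70 and 4.74, where the 20 h arrays ran from 5.92 to 6.47. CCR6 was 7.59 and 2.86. With 1 array each these are values without a test.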
